A study of Rattus norvegicus with 33 samples.

How the data were processed

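Liver RNA of 24 rats was hybridised to printed oligonucleotide slides that carry 2 dyes, so each array compares 1 rat labelled with Cy5 with another labelled with Cy3. Every array paired a rat on the endophyte-free diet (E−) with a rat on the endophyte-infected diet (E+), and the temperatures of the pair, 21 °C or 31 °C, were the same on some arrays and different on others. The rats thus formed chains of arrays, and the contrast between heated and thermoneutral rats on 1 diet was reached through these chains, since no array holds it directly.

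The deposited values are log2 ratios of the 2 channels, in 33 columns over 26911 probes. Per the labels, RNA was extracted with a Qiagen kit and channel 1 held Cy5. The design text states that intensity-based LOWESS was applied in J/MAANOVA to the data as submitted, with array as a random and dye and treatment as fixed terms, permutations in the ANOVA and a step-up false discovery rate. The table therefore held ratios from before that normalization. Array medians ran from -0.887 to 0.414, and 73 values were exactly 16.61, the log2 of 100000, and were set to missing as capped. The scanner software, background correction and filter on dim spots are not given in the sources used here. That the values are log2 was read from the cap; their centring was read from the medians; whether a column is Cy5 over Cy3 or the reverse is stated nowhere and stays unknown.

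For this reason effects are given as sizes, without a statement of which group was higher. Each effect is placed alongside Hspa8, when it had the same sign as the effect of heat on the Hspa8 probe, or opposite Hspa8. Hspa8 was chosen for this after the values had been seen, and it fixes relative direction only. If the ratios are Cy5 over Cy3, the side of Hspa8 means lower in heated rats, and in the reverse case higher. Turning the sign of every array would leave all sizes, p-values and these sides as they are.

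Between 7205 and 26236 probes had a value on an array. The columns of the pair of rats 1 and 12 held 16617 and 26236 values, and all 16617 shared ones were identical, so this array was counted once. Rats 6 and 30 carry different treatments in the titles of different arrays, and 3 of their 5 arrays were left out: those of rat 6, and the 1 that titles rat 30 as heated. The other 2 arrays of rat 30, both titled E+ thermoneutral, were kept, so that title was taken as right. One of these is the widest array of all. The fit held 29 arrays and 23 rats (5 E− and 6 E+ thermoneutral, 6 E− and 6 E+ heated), each rat on 1 to 3 arrays, in 2 chains of 12 and 11 rats with no array between them. Each array was centred on its median. The plan had been to take the values as deposited, with centring as an alternative; this was exchanged once the table proved not to be normalized, before any test was run.

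Probes with a value on at least 15 arrays were tested, 18647 in all. The model had a coefficient for each group, a common dye term, and a random rat term whose variance relative to the array error was estimated over all probes by restricted maximum likelihood. That ratio was estimated as 0, so arrays entered as independent. With the leading pattern of the arrays, their first principal component, removed, the ratio was instead estimated as 0.05. In those values arrays sharing a rat were more correlated with that rat in the same dye than in opposite dyes, by 0.133 (permutation p 0.0104). The permutation took pairs that share arrays and rats as independent. A rat shared in the same dye also brings its group in that dye, so groups and single rats are not told apart. An effect of single rats is therefore not excluded. Each probe's generalised least squares fit was moderated with limma's eBayes (limma 3.58.1 in R 4.3.3; prior degrees of freedom 3.58), 2-sided, with Benjamini-Hochberg adjustment over probes and a threshold of 0.05. The fit was written in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6, and its p-values were checked against limma, with differences of at most 3.82e-14 in log10 p. Figures were drawn with matplotlib 3.10.9.

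Lists of genes for liver pathways, stress responses and cell types, 29 in all with 822 genes, were fixed before the data were examined. Of these genes 547 were measured, and 27 lists had the 5 measured genes a test needed. Probes of a gene were averaged, giving 12667 genes, and each list was set against all other genes with camera at a preset inter-gene correlation of 0.01, then with an estimated correlation. Lists were also tested with fry over the 1151 genes with a value on every array, which left 6 lists. Genes were named by a rule fixed at the same time. It takes for each contrast up to 8 genes per direction with the largest change past the threshold, filled up by smallest p where fewer passed. It adds members of lists past the threshold, up to 4 per list, and the 3 members with the smallest p of each list that passed. For the interaction it takes the 5 genes with the smallest p. A gene is represented by its probe with the smallest p.

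The probe annotation is that of mouse genes: 20490 probes had 1 symbol, 58 several and 6363 none, and none of 20111 accessions was found in the rat RefSeq table (0 matches). Of 17061 symbols, 14354 are also used for a rat gene. Symbols are therefore those of the annotation, and which transcript of the rat each probe binds was not tested. Probes of the same gene had a median correlation of 0.252 over arrays (1015 pairs), against 0.031 for 2000 random pairs. Genomic positions are not given for the probes, since no accession was found there and placing probes by symbol or sequence was not tried.

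On simulated arrays of the same layout, 7.46% of changes of size 0.50, 55.2% of size 1.00 and 93.9% of size 2.00 (log2) were recovered in the contrast of heat on the E− diet, with 2.80% of calls false. In the contrast of diet at 21 °C 8.96%, 50.7% and 89.4% were recovered, with 6.60% of calls false. With a rat variance ratio of 0.2 in the simulation, 9.00% of calls were false for heat on the E− diet and 6.74% for diet at 21 °C. The simulated noise was independent between probes and of equal size on all arrays, unlike that of the real arrays. Recovery and false calls in the real data may therefore differ. The number of arrays limits the precision: the median standard error of a probe was between 0.17 and 0.30 (log2) over the contrasts.

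Alternatives fixed in advance covered the rat term, the arrays with conflicting titles, the doubly deposited array, centring and scaling, the dye term, the filter on missing values, moderation, arrays that hold a contrast directly, the threshold, the correlation in the list test, 1 probe per gene and each rat left out in turn. Added after the data were seen were removal of the leading pattern of the arrays, removal of a trend along the order of spots, weights per array, sparse arrays left out, the widest array left out, capped values kept and a rat variance ratio of 0.5. For each result 100 splits of the rats into groups of the same sizes, the real one included, were fitted.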

Results

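Liver of rats was sampled after 8 days on ground fescue seed with or without the fungal endophyte that makes ergot alkaloids. The infected diet supplied 91.5 µg of ergovaline per kg body weight per day. After 5 days at 21 °C part of the rats were kept at 31 °C for the remaining 3 days. The fit held 5 E− and 6 E+ thermoneutral rats and 6 E− and 6 E+ heated rats. Of the 29 arrays, 15 paired a heated with a thermoneutral rat, with the heated rat in Cy5 on 8 and in Cy3 on 7, and 14 paired rats of 1 temperature. Values per array numbered 7205 to 26236 of 26911 probes, and array medians before centring lay between -0.887 and 0.414.

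The deposited ratios carry no stated direction, so sizes are on the log2 scale and each effect is placed alongside or opposite Hspa8, the constitutive cytosolic chaperone whose probe had among the smallest p-values for heat on either diet. Ratios of different arrays were correlated between -0.744 and 0.869 (Spearman), with 50 of 496 pairs below -0.3. Every array that paired a heated with a thermoneutral rat showed Hspa8 on the same side when its sign was turned by which rat was heated (15 of 15). For the 14 arrays that paired rats of 1 temperature the direction relative to other arrays is unsettled. Without these 14 arrays, heat on 1 diet, diet at 1 temperature and the interaction cannot be estimated. Both against neither can, as can E− heated against E+ thermoneutral rats and the average effects of heat and of diet. The values printed for every contrast come from a fit that includes the 14 arrays, and hold as given only if all arrays share a direction. Array counts given for heat on either diet refer to the same 15 arrays. Each of these also differed in diet, 10 pairing E− heated with E+ thermoneutral rats and 5 the reverse, so none is specific to a diet.

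The first question is what heat did in rats on the endophyte-free diet. The Hspa8 probe changed by 1.74 ± 0.22 (SE, 3.35-fold), with an adjusted p of 0.00012 (limma) and 15 of 15 arrays on its side. Alongside it changed Hsp90aa1, an inducible cytosolic chaperone (1.37 ± 0.24, 14 of 14 arrays), Hsph1, a nucleotide exchange factor for such chaperones (1.78 ± 0.33, 11 of 12), and Ahsa1, an activator of the Hsp90 ATPase (0.86 ± 0.16, 12 of 12). Opposite Hspa8 changed Tymp, thymidine phosphorylase (1.61 ± 0.20, adjusted p = 5.67e-05, 15 of 15), and Car3, the carbonic anhydrase abundant in liver and muscle (1.89 ± 0.33, adjusted p = 0.0116, 12 of 12).

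By list, 5 of 20 measured heat shock and chaperone genes passed over all genes and 6 when adjusted over the list alone, all alongside Hspa8, while 14 did not pass. The list as a whole moved (camera t 5.74, adjusted p = 2.59e-07, and adjusted p = 0.0454 with an estimated correlation). The ER stress and unfolded protein response list followed on the same side (t 5.12, adjusted p = 4.17e-06, adjusted p = 0.239 with an estimated correlation). Of its 16 genes 2 passed over all genes and 7 adjusted over the list alone, among them Creld2, a secreted protein of the ER stress response (0.78 ± 0.15, 14 of 14 arrays), and Hyou1, an ER chaperone (0.63 ± 0.13, 11 of 13). For Pdia4, a protein disulfide isomerase, the value was 0.71 (adjusted p = 0.162, 13 of 14). Fatty acid oxidation and ketogenesis moved alongside Hspa8 (t 4.87, adjusted p = 1.03e-05, adjusted p = 0.331 with an estimated correlation). None of its 26 genes passed over all genes (0), and 8 did adjusted over the list alone. Among them were Fabp1, the liver fatty acid binding protein (1.80 ± 0.43), Cpt1a, which admits fatty acids to mitochondria (0.81 ± 0.21), and Acadl, an acyl-CoA dehydrogenase (0.87 ± 0.24). Of the circadian clock list (t 2.93, adjusted p = 0.0185, adjusted p = 0.239 with an estimated correlation) 1 of 15 genes passed over all genes, Per2, a repressor of the clock (1.82 ± 0.29, adjusted p = 0.00479, 13 of 13). Adjusted over the list alone 3 passed, with Per3 (1.48 by its best probe) and Nampt, a NAD synthesis enzyme (0.84), beside it. Respiratory chain and ATP synthase genes moved as a list by a mean of only 0.14 ± 0.03 (t 3.01, adjusted p = 0.0177, adjusted p = 0.907 with an estimated correlation), with 0 of 48 past either adjustment. Ndufb5 was at 0.47 and Atp5pb at 0.51 alongside, and Sdha at 0.29 opposite. The cell cycle list passed narrowly (t 2.60, adjusted p = 0.0421, adjusted p = 0.258 with an estimated correlation), with 0 of 14 genes past over all genes and 1 adjusted over the list alone, the replication helicase gene Mcm6 (1.54 ± 0.46, but 0.61 without rat 20). Ccnd1 was at 0.49 and Ccna2 at 0.64. Leaving out 1 rat ended the list call for fatty acid oxidation (rat 26, t 2.38) and circadian clock (rat 4, 9, 10, 14, 20, 22, 26 or 29, t down to 2.29). The same held for respiratory chain (rat 4, 10, 12, 14, 15, 17, 21, 22, 26 or 29, t down to 0.965) and cell cycle (rat 4, 9, 10, 14, 15, 17, 20, 21, 22, 26, 27 or 29).

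Outside these lists C730007P19Rik, a gene without an established function (2.32 ± 0.47, adjusted p = 0.0292, 12 of 14 arrays), Nat8, an ER-bound N-acetyltransferase (1.66 ± 0.28, 13 of 13), Paqr9, a membrane receptor family member (1.33 ± 0.24, 10 of 13), and Apoa1, the main protein of HDL (1.24 ± 0.24, 13 of 15), changed alongside Hspa8. Hsd11b1, which regenerates active glucocorticoid, had a value of 1.03 opposite Hspa8 without passing (adjusted p = 0.127, 9 of 14). Jun (0.85, adjusted p = 0.135, 10 of 13), Cmtm6 (0.60, adjusted p = 0.137, 15 of 15), Exosc4 (1.02, adjusted p = 0.137, 7 of 10), Selp (0.92, adjusted p = 0.221, 10 of 11) and Arhgef19 (1.01, adjusted p = 0.237, 11 of 12) had values on that side too. The smallest p of the contrast belonged to probe 17516, which has no gene name (2.02 ± 0.18, adjusted p = 2.90e-07). In all 26 probes passed, 24 of them alongside Hspa8 and 2 opposite, for 21 named genes. The count depends on single animals and on the rat term. It was 5 without rat 20, 6 without rat 22, 9 without rat 10, 10 without rat 29 and 12 without rat 1, 8, 12 or 17. It was 13 without rat 11, 16 or 21 and 15 without rat 15 or 18, and 1 with each rat as a fixed effect. Tymp, Hspa8 and Per2 passed whichever rat was left out, and every other gene named here as changed failed without each of several rats taken singly. The number of lists, 6 of 27, was 2 without rat 26, 3 without rat 4, 10, 14, 22 or 29 and 10 without rat 5, 8, 13 or 30.

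**Figure D1:**
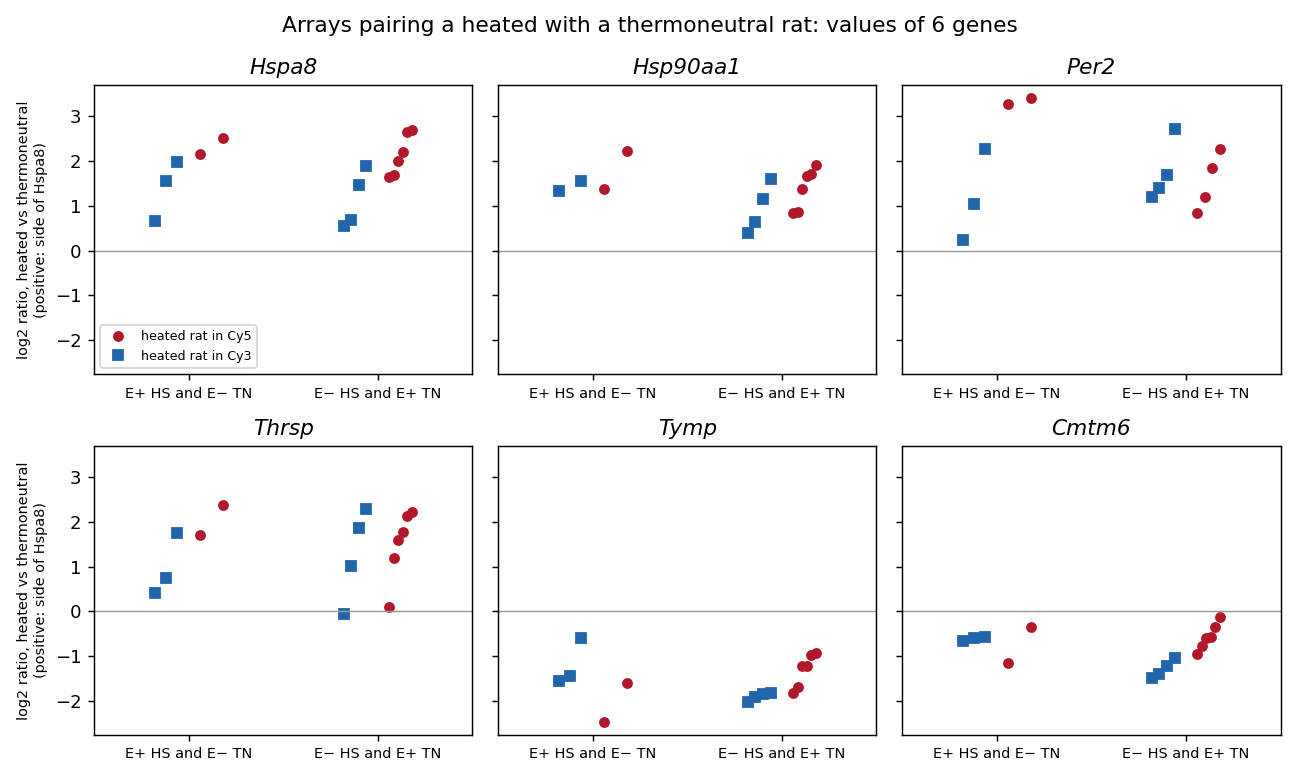
Centred log2 ratio of heated against thermoneutral rat on the 15 arrays that pair such rats, for 6 genes, with the side of Hspa8 drawn as positive, each point being 1 array, red with the heated rat in Cy5 and blue in Cy3. All values of Hspa8, Hsp90aa1 and Per2 lie above 0, 14 of 15 of Thrsp do, and all of Tymp and Cmtm6 lie below.

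The same question was asked in rats on the infected diet. Heat changed the Hspa8 probe by the same size there, 1.74 ± 0.22 (adjusted p = 0.000119, 15 of 15 arrays), and Hsp90aa1 by 1.46 ± 0.24 (adjusted p = 0.00418, 14 of 14). With the 2 probes of Hspa8 averaged, sizes were 1.63 ± 0.25 on the E− and 1.91 ± 0.24 on the E+ diet. Beside them changed Alas1, the rate-limiting enzyme of heme synthesis (1.43 ± 0.20, adjusted p = 0.00036, 14 of 15), Thrsp, a regulator of lipogenesis (1.72 ± 0.27, adjusted p = 0.00154, 14 of 15), and Fdps, farnesyl diphosphate synthase of the cholesterol pathway (1.14 ± 0.20, adjusted p = 0.00632, 14 of 15). Opposite Hspa8 changed Insig2, which holds back sterol synthesis (1.41 ± 0.23, adjusted p = 0.0038, 10 of 13), and Tymp (1.49 ± 0.19, adjusted p = 0.000119, 15 of 15).

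Cholesterol synthesis had the largest list statistic (t 5.32, adjusted p = 2.88e-06, adjusted p = 0.141 with an estimated correlation), with 17 of 19 genes alongside Hspa8. The call depends on the direction of the arrays that pair rats of 1 temperature. With those of either of 2 opposing sets of arrays turned, the camera t was 1.29 (adjusted p 0.335) or 2.60 (adjusted p 0.0276). With those of both sets turned it was -0.878 (adjusted p 0.540). With probes averaged 0 of the 19 genes passed over all genes, and 3 did adjusted over the list alone: Fdps, Cyp51, lanosterol demethylase (0.89 ± 0.22), and Idi1, isopentenyl diphosphate isomerase (1.42 ± 0.40). The fatty acid synthesis list passed narrowly (t 2.54, adjusted p = 0.0433, adjusted p = 0.528 with an estimated correlation). Of its 16 genes 1 passed over all genes, Thrsp, and 4 adjusted over the list alone. These were Thrsp, Fasn, fatty acid synthase (1.25 ± 0.34), and the desaturase Fads1 (1.19 ± 0.27, adjusted p = 0.0692 over all probes, 14 of 15) alongside, and Agpat2 opposite (0.45). Of the heat shock and chaperone list (t 5.03, adjusted p = 4.49e-06, adjusted p = 0.128 with an estimated correlation) 2 of 20 genes passed over all genes and 5 adjusted over the list alone. Among the 5 was the co-chaperone Stip1 at 0.59 ± 0.16 (10 of 10 arrays). The ER stress list (t 5.04, adjusted p = 4.49e-06, adjusted p = 0.194 with an estimated correlation) had 0 of 16 genes past over all genes and 5 adjusted over the list alone. Among these were Creld2 (0.55), Hsp90b1, an ER chaperone (0.80), and Herpud1, of ER-associated degradation (0.78). With the arrays of 1 temperature turned in 1 of the opposing sets, the ER stress list did not pass (camera t 2.24, adjusted p 0.0847). It did with those of the other set (t 6.41) or of both sets turned (t 4.82). Of the circadian clock list (t 3.26, adjusted p = 0.00609, adjusted p = 0.13 with an estimated correlation) Per2 (1.84 ± 0.29, adjusted p = 0.00222, 13 of 13) and Bhlhe40, a repressor of the clock (1.41 ± 0.26, adjusted p = 0.0107, 12 of 13), were the 2 of 15 genes that passed over all genes. Adjusted over the list alone 5 passed, Per1 (0.39) and Per3 (1.46 by its best probe) with them alongside Hspa8 and Nr1d1, whose product acts against the activators of the clock, opposite (0.70).

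By camera the respiratory chain list had a t of 3.90 (adjusted p = 0.00064, adjusted p = 0.768 with an estimated correlation). The ribosomal protein list had a t of 2.48 (adjusted p = 0.0441, adjusted p = 0.873 with an estimated correlation). Their means were 0.16 ± 0.04 and 0.10 ± 0.03 (SE over genes, which are not independent replicates). Past either adjustment were 0 of 48 and 0 of 58 genes. Of 100 splits of the rats 18 and 46 gave a t as large, so chance is not excluded for either list. Ndufa9 (0.66, 11 of 11 arrays) and Cox8a (0.79) lay alongside Hspa8 and Sdha (0.44) opposite. Among ribosomal genes Rpl31 (0.62) and Rps10 (0.29, but 0.16 without rat 5) lay alongside and Rpl13a (0.30) opposite. Acute phase and inflammation moved opposite Hspa8 (t 2.84, adjusted p = 0.02, adjusted p = 0.405 with an estimated correlation): of 25 genes 0 passed over all genes and 1 adjusted over the list alone. It was complement factor B (Cfb, 2.22 ± 0.57), with Il1r1 at 0.78 and C4a at 0.93 on its side. Leaving out 1 rat ended the list call for respiratory chain (rat 5, t 1.30) and acute phase (rat 1, 8, 9, 14, 16, 22 or 29, t down to 1.73). The same held for fatty acid synthesis (rat 5, 8, 9, 13, 16, 17, 21, 22, 27, 29 or 30, t down to 1.80) and ribosomal proteins (rat 3, 5, 9, 11, 13, 17, 21, 26, 27, 28 or 30). Without rat 5 the sign of the latter turned, at t -0.864.

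Further genes changed alongside Hspa8 were Nat8 (1.65 ± 0.27, 13 of 13 arrays) and Mfsd2a, a lysophospholipid transporter (1.43 ± 0.29, 11 of 12). Opposite it changed Rnf125, a ubiquitin ligase (1.31 ± 0.27, 12 of 15), Sult1c2, a sulfotransferase (1.23 ± 0.24, 11 of 13), Atp2b3, a calcium pump (1.14 ± 0.23, 10 of 10), Cmtm6 (0.91 ± 0.14, adjusted p = 0.0018, 15 of 15), the adhesion molecule gene Nectin2 (0.68 ± 0.12, 13 of 14) and a probe of the olfactory receptor Olfr531 (0.70 ± 0.14, 7 of 9). In all 27 probes passed, for 20 named genes, 18 alongside Hspa8 and 9 opposite (66.7% alongside). With the values as deposited, whose median effect differs by 0.12, the split was 32 and 4 (88.9%). The count was 15 without rat 8, 16 without rat 11 and 5 with each rat as a fixed effect, and 8 of 27 lists passed. Tymp, Hspa8, Per2, Thrsp, Alas1, Insig2, Cmtm6, Nectin2 and Nat8 passed whichever rat was left out. Fdps failed only without rat 27, and every other gene named here as changed failed without each of 2 or more rats taken singly.

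Between the diets, 9 probes were called for heat in both contrasts, all 9 with the same sign, where independent lists would share 0.0241 with the same sign. The contrasts share arrays, and log2 fold changes over all probes correlated at 0.159, against a mean of 0.0645 and a highest value of 0.0888 in 20 simulated tables with no effect. These tables held noise independent between probes and of equal size on every array. The real arrays share a pattern over probes and differ in spread, so the correlation with no effect may lie higher. The covariance was 0.0113 against 0.00673 from the shared arrays. Genes are not independent replicates, and part of the overlap may come from the shared arrays.

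**Figure D2:**
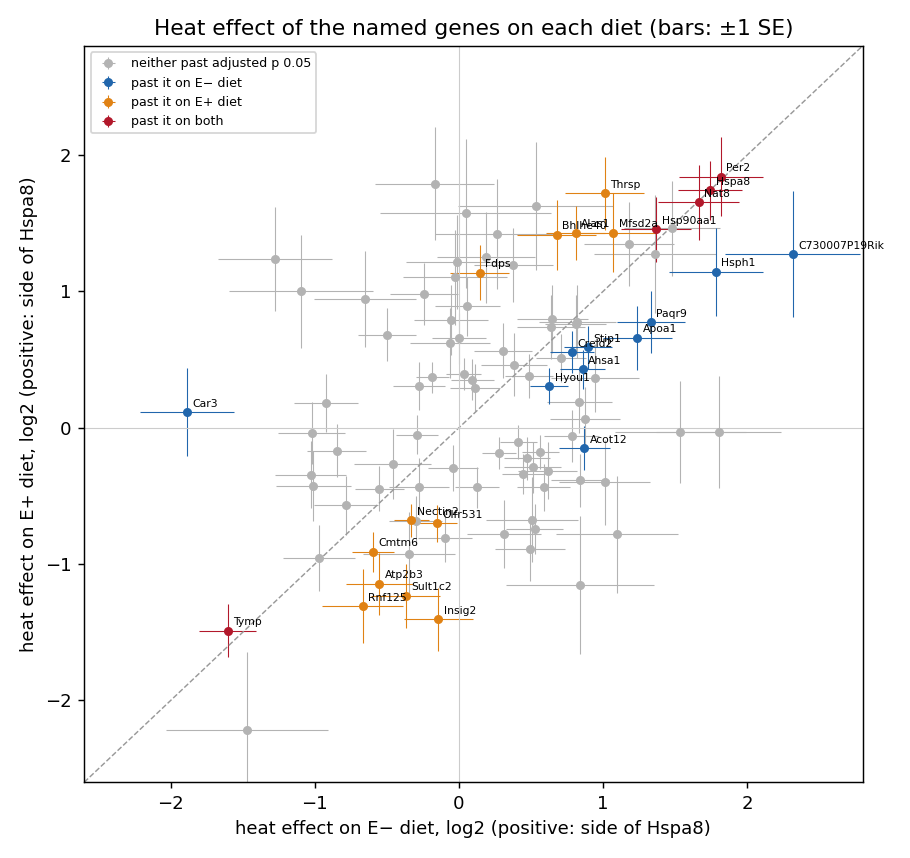
Log2 effect of heat on the E− diet (x axis) and on the E+ diet (y axis) for the named genes, the side of Hspa8 drawn as positive, with bars of 1 SE, the dashed line marking equal effects and colours marking the diet on which a gene passed. Hspa8 lies at 1.74 on both axes, while Car3 lies at a size of 1.89 on the x axis and 0.12 on the y axis.

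Whether diet altered the liver without heat was asked in the thermoneutral rats. No single probe passed, and the cholesterol synthesis genes stood out as a list. Of 19 genes 16 had values opposite Hspa8, with a mean of 0.30 ± 0.06 (SE over genes, t 5.31, adjusted p = 2.99e-06). That list's adjusted p = 0.427 with an estimated correlation. Its t, signed by the main value, was -0.813 or 1.34 with the single-temperature arrays of either opposing set turned. With those of both sets turned it was -5.09 (adjusted p = 9.58e-06), so the call and its side depend on their direction. None passed over all genes (0), and 3 did adjusted over the list alone. These were Insig1, a paralog of Insig2 (1.08 ± 0.31 by its best probe, 4 of 6 arrays holding the contrast directly), Cyp51 (0.62 ± 0.20, 5 of 5) and Tm7sf2, a sterol reductase (0.70 ± 0.23). Fdps had a value of 0.73 ± 0.19 on the same side (6 of 6).

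The gene with the smallest p was Car3 (1.53 ± 0.30 opposite Hspa8, adjusted p = 0.523, 4 of 5 direct arrays). On its side lay Cyp2b10, a cytochrome P450 of drug metabolism (1.36, 5 of 6), Hsd11b1 (0.84, 6 of 6), Tmem161a (0.68, 6 of 6), Exosc4 (0.90, 3 of 3), Mindy1 (1.66, 1 of 1) and the glycolytic enzyme Gapdh (0.69, 3 of 4), with adjusted p-values from 0.635 to 0.954. Alongside Hspa8 lay Acot12, a cytosolic acetyl-CoA hydrolase (0.71, 4 of 4), Mrpl52 (0.76, 5 of 6), Nae1 (0.57, 6 of 6) and Nelfe (0.72, 6 of 6). So did Unc119b (1.47, 5 of 6), Cops2 (0.44, 5 of 6), Ctnnd1 (0.78, 1 of 2) and Msn (1.71, 5 of 6), with adjusted p-values in the same range. Without rat 9 the values fell to 0.93 for Car3, 0.39 for Tmem161a, 0.48 for Fdps, 0.64 for Mindy1, 0.46 for Gapdh and 0.29 for Cops2. The number of probes past the threshold was 0 by limma, with a smallest adjusted p of 0.523. It was 1 without rat 15, 17 or 18 and 2 without rat 26. At an unadjusted p under 0.05 were 816 probes, fewer than the 5% of 18647 tested that chance gives on average. The single list became 2 without rat 1, 4, 8, 10, 12, 14, 15, 20, 21, 22 or 26, 3 without rat 5 or 13, 6 without rat 9 and 7 without rat 30.

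The same diets were compared under heat, the condition in which fescue toxicosis is most evident. No gene and no list passed. The genes with the smallest p, none past the threshold, included alongside Hspa8 Ccdc85a (1.32, 5 of 6 direct arrays), the neuronal transcription factor Npas3 (1.24, 4 of 5), A230006K03Rik (1.14, 4 of 5), Tnfsf4 (1.06, 4 of 6) and Bcl2, which holds back apoptosis (0.95, 5 of 6). On that side were also 2410137M14Rik (0.71, 4 of 7), the homeobox gene Dlx3 (0.37, 6 of 7) and Gtf2h1 (0.34, 5 of 7). Opposite lay Gch1, the first enzyme of tetrahydrobiopterin synthesis (1.09, 5 of 6), Sptssa, a subunit of serine palmitoyltransferase (0.98, 4 of 7), Vamp7 (0.80, 3 of 5) and Nudt3 (0.67, 3 of 4), and further Ube2d1 (0.54, 4 of 6), Usp9x (0.53, 2 of 5), Gt4-1 (0.35, 7 of 8) and Metap2 (0.34, 5 of 8). Without rat 10 the values fell to 0.42 for Nudt3 and 0.73 for A230006K03Rik. By limma 0 probes passed, with 549 at an unadjusted p under 0.05, and every adjusted p rounded to 1.00. The 549 are fewer than the 5% of 18647 tested probes that chance gives on average. The smallest list adjusted p was 0.213, for cholesterol synthesis and for urea cycle and amino acid catabolism. The list count of 0 became 1 without rat 11, 27 or 28, 2 without rat 4, 10 or 13 and 3 without rat 5.

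Whether heat acted differently on the diets was tested as an interaction. The cholesterol synthesis list differed (t 5.18, adjusted p = 5.93e-06, adjusted p = 0.489 with an estimated correlation). In 17 of 19 genes the heat effect on the E+ diet lay further to the side of Hspa8 than that on the E− diet. The mean difference over all 19 genes was 0.40 ± 0.10 (SE over genes). With the single-temperature arrays of either opposing set turned, the signed t was -1.14 or 0.948, and the call was lost. With those of both sets turned it was -5.70 (adjusted p = 3.29e-07), a call on the other side. No member passed over all genes (0) or adjusted over the list alone (0). For Fdps the heat effect was 0.14 on the E− and 1.14 on the E+ diet, with a difference of 0.99 ± 0.29. For Cyp51 it was 0.06 and 0.89, with a difference of 0.83 ± 0.31, and neither difference passed. Insig2 stood at 0.14 and 1.41, both opposite Hspa8 (difference 1.26 ± 0.33, adjusted p = 0.895).

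Car3 had an effect of heat of 1.89 opposite Hspa8 on the E− diet and of 0.12 alongside it on the E+ diet, and the difference, with an SE of 0.46, did not pass (adjusted p = 0.895) and was 1.29 without rat 9. The other genes with the smallest p were Ctnnd1 (1.27 ± 0.30), the mitochondrial ribosomal gene Mrpl52 (1.22 ± 0.27), Acot12 (1.02 ± 0.23) and the methionine aminopeptidase Metap2 (0.74 ± 0.16), all opposite Hspa8 and with an adjusted p of 0.895. For the chaperones no difference was detected. That of the Hspa8 probe with the smallest p was 0.00 ± 0.32, and the heat shock and chaperone list had an adjusted p of 0.732 by camera. By gene, heat effects were larger on the E− than the E+ diet for Hsph1 (1.78 and 1.14) and Ahsa1 (0.86 and 0.43). They were smaller for Hsp90aa1 (1.37 and 1.46) and for Hspa8 with probes averaged (1.63 and 1.91). Equal effects on the diets are therefore not shown. By limma 0 probes passed, with 641 at an unadjusted p under 0.05, again fewer than 5% of the 18647 tested. The 1 list became 3 without rat 4, 4 without rat 9 or 30 and 5 without rat 5.

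Rats with both heat and the infected diet were set against rats with neither. The chaperone genes changed again, Hspa8 by 1.77 ± 0.21 (adjusted p = 2.57e-05, 5 of 5 direct arrays), Hsp90aa1 by 1.62 ± 0.23 (adjusted p = 0.00101, 4 of 4) and Hsph1 by 1.75 ± 0.32 (adjusted p = 0.017, 4 of 4). ER stress genes formed the list with the largest statistic (t 6.35, adjusted p = 6.01e-09, adjusted p = 0.0684 with an estimated correlation), with Creld2 (0.90 ± 0.14, 5 of 5), Pdia4 (0.88 ± 0.16, 5 of 5) and Hyou1 (0.64 ± 0.12, 5 of 5) past the threshold over all genes. Of its 16 genes 7 passed adjusted over the list alone. Opposite Hspa8 changed Tymp (1.56 ± 0.19, adjusted p = 2.57e-05, 5 of 5), Car3 (1.42 ± 0.30, adjusted p = 0.0422, 5 of 5) and Hsd11b1 (1.18 ± 0.24, adjusted p = 0.0243, 5 of 5).

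The heat shock and chaperone list moved (t 5.90, adjusted p = 5.08e-08, adjusted p = 0.0361 with an estimated correlation), with 5 of 20 genes past over all genes and 6 adjusted over the list alone, Ahsa1 among them (0.84 ± 0.16, 3 of 3). Of fatty acid oxidation (t 4.87, adjusted p = 1.03e-05, adjusted p = 0.331 with an estimated correlation) 1 of 26 genes passed over all genes, Cpt1a (0.98 ± 0.20, 5 of 5). Adjusted over the list alone 6 passed, with Cyp4a10, a fatty acid hydroxylase (1.81 ± 0.38, adjusted p = 0.075 over all probes), and Eci1 (1.00 ± 0.30). The circadian clock list (t 3.57, adjusted p = 0.00245, adjusted p = 0.0684 with an estimated correlation) had 1 of 15 averaged genes past over all genes and 7 adjusted over the list alone. These were Per1 (0.38), Per2 (1.87 ± 0.27), Per3 (1.71 ± 0.34 by its best probe, which passed with an adjusted p of 0.0386 and stood at 1.09 without rat 20), Dbp (1.09), Bhlhe40 (1.03) and Nampt (0.62) alongside Hspa8, and the clock activator Arntl (0.64) opposite. Respiratory chain genes moved as a list (t 2.92, adjusted p = 0.0192, adjusted p = 0.85 with an estimated correlation) with 0 of 48 past either adjustment. Ndufa10 was at 0.71 (0.27 without rat 9), Cox6c at 0.47 and Ndufa5 at 0.32. Urea cycle and amino acid catabolism lay opposite (t 2.54, adjusted p = 0.0496, adjusted p = 0.85 with an estimated correlation), with 0 of 30 genes past over all genes and 1 adjusted over the list alone. It was Gnmt, glycine N-methyltransferase (0.71 ± 0.20, 5 of 5), with Gpt at 0.65 (0.42 without rat 9) and Agxt at 0.41. Leaving out 1 rat ended the list call for fatty acid oxidation (rat 26, t 1.97) and circadian clock (rat 26, t 2.42). The same held for respiratory chain (rat 5, 8, 11, 14, 15, 16, 17, 21, 22, 26 or 27, t down to 1.07) and urea cycle (rat 1, 4, 8, 9, 14, 16, 18, 20, 26, 28, 29 or 30). Without rat 9 the sign of the latter turned, at t -0.858.

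Paqr9 (1.47 ± 0.22, 5 of 5 direct arrays), Nat8 (1.43 ± 0.27, 4 of 4), Ppp1r3b, a glycogen-targeting phosphatase subunit (1.36 ± 0.29, 5 of 5), Thrsp (1.26 ± 0.26, 5 of 5) and Apoa1 (1.12 ± 0.23, 5 of 5) also changed alongside Hspa8, and Nectin2 opposite (0.60 ± 0.12, 5 of 5). Cmtm6 (0.64, adjusted p = 0.0502), Gldc of glycine cleavage (0.99, adjusted p = 0.0613), choline kinase Chka (0.99, adjusted p = 0.135) and P2rx7 (0.63, adjusted p = 0.162) had values opposite Hspa8 without passing. In all 35 probes passed, for 30 named genes, 31 alongside Hspa8 and 4 opposite. Of the arrays 5 held the contrast directly, and with those alone 2 probes passed. The 18 calls of named genes that could be tested there kept their sign, but none of them passed. The count was 8 without rat 8, 12 without rat 20, 13 without rat 17 or 21, 14 without rat 11 or 16 and 17 without rat 13. It was 18 without rat 22, 19 without rat 9, 22 without rat 10, 23 without rat 1 and 1 with each rat as a fixed effect. Tymp, Hspa8 and Paqr9 passed whichever rat was left out, and Per2, Hsp90aa1 and Creld2 failed only without rat 8. Every other gene named here as changed failed without each of 2 or more rats taken singly. The 6 lists became 2 without rat 26 and 10 without rat 9.

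**Figure D3:**
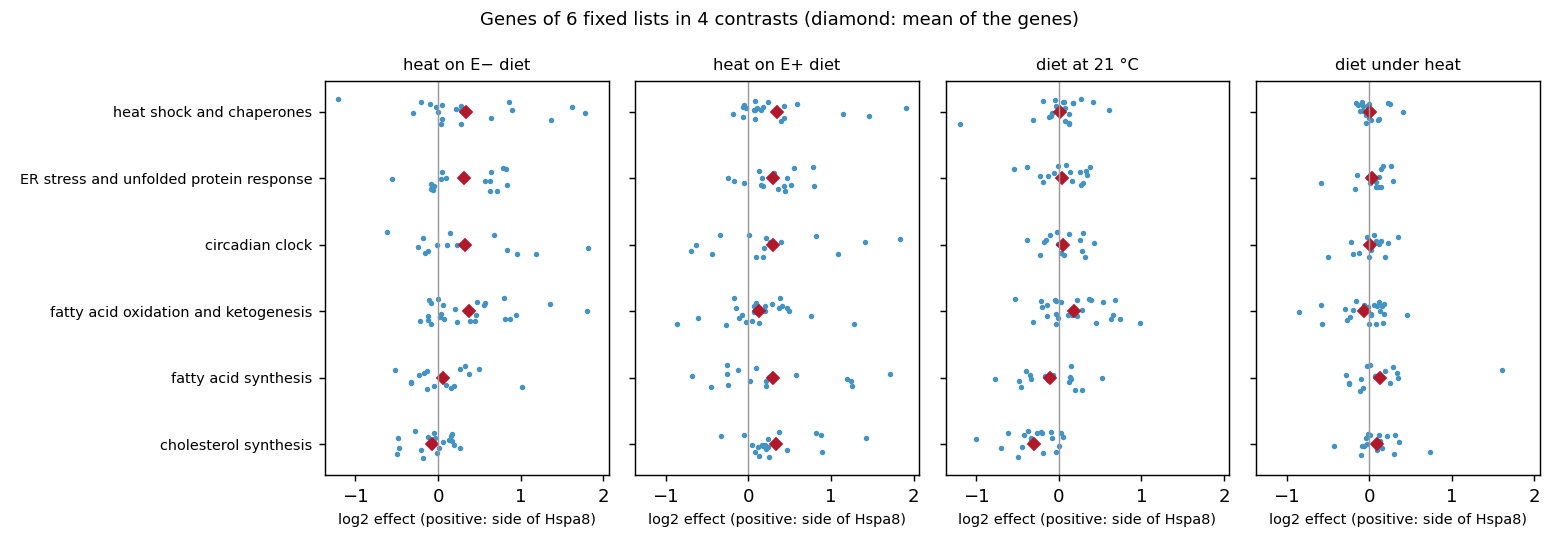
Log2 effects of the genes of 6 lists in 4 contrasts, the side of Hspa8 drawn as positive, where each dot is 1 gene and each diamond the mean of a list. The mean of cholesterol synthesis lies at a size of 0.30 below 0 for diet at 21 °C and at 0.33 above 0 for heat on the E+ diet.

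Marker lists of liver cell types, white blood cells and exocrine pancreas passed in none of the 6 contrasts (0 tests of 8 lists by camera), and their smallest adjusted p was 0.188, for hepatocyte markers under heat on the E− diet, where 1 gene, Apoa1, passed. Of all 162 list tests, 28 had a median, mean and test that differed in sign, 0 of them past the threshold. With an estimated correlation the heat shock and chaperone list passed for heat on the E− diet and for both against neither, and no other list did in any contrast (0 for heat on the E+ diet). By fry, which tests a list against no change and here held only the 6 cholesterol synthesis genes with a value on every array, adjusted p was 0.0131 for diet at 21 °C, 0.0247 for heat on the E+ diet and 0.0617 for the interaction.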

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

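Of the tests in this part, those for the leading pattern of the arrays, the turned ratios (of all arrays and of those of 1 temperature), the dye trend, the sign of the chaperone list by set of arrays and the splits of the heat shock and ER stress lists taken singly were chosen after the result was seen; the others were fixed before.

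In groups of 4 to 6 arrays of the same treatments and dyes, 8 values lay far from the other arrays of their group, the gap to the nearest other being given as a share of the whole range. These were Cyp2b10 (0.845, array of rats 17 and 18), Gnmt (0.848, rats 9 and 21) and Pdia4 (0.869, rats 20 and 22) among the arrays with E− thermoneutral in Cy3 and E+ thermoneutral in Cy5. Fabp1 (0.898, rats 27 and 21) lay apart among those with E− heated in Cy3 and E+ thermoneutral in Cy5. Mfsd2a (0.652, rats 29 and 3), Nectin2 (0.803, rats 4 and 10), Npas3 (0.893, rats 5 and 13) and Sdha (0.777, rats 5 and 13) were the others, with E− heated in Cy3 and E+ heated in Cy5. In all 309 groups of values were examined, and 8 are 2.59% of them, where chance gives about 5%.

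The cholesterol synthesis list gave a t of 5.18 for the interaction of diet and heat, with an adjusted p of 0.489 with an estimated correlation and no single member past the threshold. The leading pattern of the arrays is argued against, since 97.9% of the mean difference was kept once it was removed. Of 100 splits of the rats only the real one gave a t as large as 5.18 (1 split, highest other 4.67). That share is not adjusted for the 27 lists tested. With 1 rat left out the t was lowest at 3.34 (rat 9). This lies below the highest other split, so a part played by 1 rat is not excluded. Turned ratios stay open, because the interaction cannot be estimated without the arrays that pair rats of 1 temperature, and with those of 1 opposing set turned its t, signed by the main value, fell to -1.14, and with those of both sets turned it was -5.70 (adjusted p 3.29e-07), a call on the other side. The list's t, as a size, was also large for diet in thermoneutral rats (5.31) and for heat on the E+ diet (5.32). Like the interaction, both contrasts include the E+ thermoneutral group. In contrasts lacking it, t was 0.435 for both against neither, 1.30 for heat on the E− diet and 2.41 for diet under heat. These values do not separate an altered response to heat from a difference of E+ thermoneutral rats alone. An effect of the infected diet on sterol synthesis, directly or through feed intake, was not tested. It may account for the difference only if the arrays that pair rats of 1 temperature share a direction.

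The heat shock and chaperone list and the ER stress list passed for heat on either diet, but with an estimated correlation only the former did, on the E− diet (adjusted p 0.0454, against 0.128 on the E+ diet, and 0.239 and 0.194 for ER stress). At least 92.7% of the mean shift was kept once the leading pattern of the arrays was removed, which argues against that pattern. With 1 rat left out the t was lowest at 3.08 for the ER stress list (E− diet, rat 26). For the heat shock and chaperone list it was lowest at 3.91 (E+ diet, rat 8). These lie below the highest other split of the same list and diet (5.53 and 4.47). A part played by 1 rat is therefore not excluded. Of 100 splits of the rats, the real one included, 6 gave a t as large for the ER stress list on the E+ diet, the most of these lists on either diet (highest other 6.22), whereas for the heat shock and chaperone list only the real split did on either diet (1, highest other 5.47). For the ER stress list on the E+ diet chance is therefore not excluded. A response of protein folding to heat may account for the chaperone part, as a hypothesis found and tested on the same data; the direction is open, and with ratios of Cy5 over Cy3 these genes would be lower in heated rats.

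Arrays fell into sets that oppose each other: 53.6% of the variance of the ratios lay in 1 pattern, with 13 arrays loading positively and 16 negatively. That the ratios of 1 set were turned is argued against, but not excluded, for the 15 arrays that pair a heated with a thermoneutral rat. There the heat shock and chaperone list lay on the Hspa8 side on 7 of 7 and 8 of 8 arrays of the opposing sets. The larger exact sign test p was 0.0156, 2-sided, the smallest that 7 arrays can give. The list includes Hspa8, chosen after the values were seen, and the lowest of the array means was 0.03. Arrays within a set share rats, so the sign test, which takes them as independent, may overstate the evidence. The list without Hspa8 was not tested. Turned ratios stay open for the other 14 arrays. With the leading pattern removed, pairs of arrays from opposing sets that share a rat correlated higher by 0.0842 with the rat in the same dye than in opposite dyes (permutation p 0.196). This decides neither way. The difference was 0.211 within a set (permutation p 0.01335) and 0.133 over all pairs (permutation p 0.0104). These permutations took pairs that share arrays and rats as independent. An intensity-dependent dye trend may underlie the pattern, because ribosomal protein and Gapdh probes lay at least 31.4 percentile points from olfactory receptor probes along it. The groups explained 5.31% of the variance of the loadings (permutation p 0.7003), which leaves a part for diet and heat open.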

How the results depend on the processing

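The alternatives chosen after the data were seen were leading pattern removed, spot-order trend removed, array weights, sparse or widest array left out, caps kept and a variance ratio of 0.5. The values as deposited were planned as the first choice and became an alternative once they proved not to be normalized, before any test; the others were planned. No paired analysis was possible because no replicate number is shared by rats of different groups, apart from the pairing of 2 rats on an array, which the fit uses throughout. Counts of probes past the threshold are given for heat on the E− diet, heat on the E+ diet and both against neither (26, 27 and 35), or by name. With each rat as a fixed effect, which leaves 5636 probes testable, they were 1, 5 and 1, and with a variance ratio of 0.5 they were 4, 12 and 8. With only the 1167 probes valued on every array they were 4, 11 and 7. Without a dye term the first and last were 15 and 22, with sparse arrays left out the first was 16, and with arrays holding the contrast directly the last was 2; heat on 1 diet was not run that way, since no array holds it. They rose to 55 and 55 (first and last) after scaling, 42 (first) with rats 6 and 30 taken as thermoneutral, 41 (second) at a threshold of 0.10, 64, 84 and 192 with array weights and 165, 240 and 180 with the leading pattern removed. In that last setting all 26, 27 and 35 probes were called again, and of the probes it called 84.8%, 68.3% and 83.3% lay alongside Hspa8. Diet at 21 °C went from 0 to 1 as deposited, 2 with the leading pattern removed and 3 with weights, and the interaction from 0 to 2 with the leading pattern removed. Fewer probes were tested with each rat fixed and with complete probes. Of the named calls still testable, 20 were lost and 5 kept with each rat fixed, while with complete probes all 9 were kept. Fewer tested probes therefore do not account alone for the drop with each rat fixed. The cause of these shifts was not tested.

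Lists past the threshold were 1 for diet at 21 °C, 0 for diet under heat, 6 and 8 for heat on the E− and E+ diet, 1 for the interaction and 6 for both against neither. With an estimated correlation they were 0, 0, 1, 0, 0 and 1. For diet at 21 °C they were 2 with 1 probe per gene, 3 as deposited, 5 after scaling, 5 with the leading pattern removed, 4 with weights and 7 without the widest array. For diet under heat they were 1 as deposited, with the leading pattern removed and with a variance ratio of 0.5, and 2 with complete probes. For heat on the E− diet they were 10 with the leading pattern removed and without the widest array and 0 with complete probes, and for heat on the E+ diet 1 with complete probes. For the interaction they were 4 after scaling, 2 with complete probes, 3 with weights and 4 without the widest array, and for both against neither 10 after scaling and 0 with complete probes. Leaving out 1 rat gave 0 to 2 probes for diet at 21 °C, 0 to 0 for diet under heat and for the interaction, 5 to 38 and 15 to 30 for heat on the E− and E+ diet and 8 to 45 for both against neither. Lists then numbered 1 to 7, 0 to 3, 2 to 10, 6 to 10, 1 to 5 and 2 to 10, in the order above. Among these alternatives signs reversed in 3 results: Cox6c, both against neither, stood at -0.0913 with rat as a fixed effect, the ribosomal protein list t for heat on the E+ diet ranged from -0.864 to 4.10 and the urea cycle list t for both against neither from -0.858 to 3.59 with 1 rat left out. Per2 and Thrsp for heat on the E+ diet passed in 42 of 42 and 43 of 43 alternatives, and the heat shock and chaperone list for heat on the E− diet in 36 of 36. With the arrays that pair rats of 1 temperature turned in either opposing set, a check added after the result was seen, the heat shock and chaperone list kept a t of at least 3.96 for heat on either diet, ER stress on the E+ diet fell to 2.24 (adjusted p 0.0847) and cholesterol synthesis for heat on the E+ diet to 1.29. Signs of cholesterol synthesis also reversed there: for the interaction (t -1.14 in 1 set, -5.70 with both sets turned), for diet at 21 °C (-0.813 and -5.09) and for heat on the E+ diet (-0.878 with both sets). Values per array, for 7205 to 26236 of 26911 probes, fell unevenly on probes: olfactory receptor probes had values on a median of 14 arrays and ribosomal protein probes on 25.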

Other observations

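The splits of the rats for counts of probes and lists were fixed before the data were examined, and those by single list were chosen after the result was seen.

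In lists that did not pass as a whole, single members passed when adjusted over the list alone. That adjustment does not cover the 162 combinations of list and contrast, so some of these members may have passed by chance. For heat on the E+ diet these were Cpt1a (0.76 alongside Hspa8), Adh1, alcohol dehydrogenase (1.62 alongside), Cyp8b1, sterol 12-hydroxylase of bile acid synthesis (1.75 opposite), liver glycogen phosphorylase Pygl (0.63 opposite) and Agxt, which detoxifies glyoxylate (0.68 opposite). For heat on the E− diet they were Slc37a4, the glucose-6-phosphate transporter (0.58 alongside), Thrsp (1.01 alongside) and Apoa1 (1.24 alongside). For both against neither they were Pygl (0.56 opposite), Cfb (2.04 opposite), Thrsp (1.26 alongside) and Apoa1 (1.12 alongside). Casp9, of the apoptosis list, was the only such member for diet at 21 °C beyond cholesterol synthesis (0.77 opposite), and Pfkfb3, of glycolysis, the only one for the interaction (0.72 opposite). Adh1, Cyp8b1, Pygl, Agxt, Slc37a4, Casp9 and Pfkfb3 passed over all genes in no contrast.

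Splits of the rats into groups of the same sizes numbered 100. Only the real one gave as many probes for heat on the E− diet (1 split, 26 probes, highest other 2). The same held for heat on the E+ diet (1 split, 27 probes, highest other 4) and both against neither (1 split, 35 probes, highest other 6). This argues against chance for these counts without excluding it, because 1 in 100 is the smallest share these splits can give. For diet at 21 °C, diet under heat and the interaction the real count was 0, which all 100 splits reach by construction, so nothing about chance follows (highest others 1, 1 and 45). The single split with 45 may point to a structure of the samples, which was not tested. Numbers of lists with a real count above 0 were reached often enough that chance is not excluded: 73 splits gave as many as the real 1 for diet at 21 °C (highest other 12), 34 as many as 6 for heat on the E− diet (13), 7 as many as 8 for heat on the E+ diet (10), 76 as many as 1 for the interaction (15) and 22 as many as 6 for both against neither (12). For diet under heat the real count of 0 is reached by all 100 splits by construction (highest other 12).

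By single list, a t as large came from these numbers of 100 splits, the real one counted, with the real t and the highest other in brackets. With heat on the E+ diet they were 46 for ribosomal proteins (2.48, 5.37), 18 for respiratory chain (3.90, 6.09), 13 for fatty acid synthesis (2.54, 3.77) and 9 for acute phase (2.84, 4.29). With heat on the E− diet they were 29 for respiratory chain (3.01, 5.38), 8 for cell cycle (2.60, 3.42) and 5 for fatty acid oxidation (4.87, 5.19). For both against neither they were 45 for urea cycle (2.54, 5.52), 29 for respiratory chain (2.92, 5.85) and 5 for fatty acid oxidation (4.87, 5.67). For circadian clock they were 3 with heat on the E− diet (2.93, 3.35), 1 on the E+ diet (3.26, 3.24) and 1 for both against neither (3.57, 2.95). For cholesterol synthesis they were 2 for diet at 21 °C (5.31, 5.32) and 4 for heat on the E+ diet (5.32, 5.54). For ER stress they were 4 with heat on the E− diet (5.12, 5.53) and 1 for both against neither (6.35, 5.59), and for heat shock and chaperones 1 for both against neither (5.90, 4.61). These lists were chosen because they passed, out of 27 per contrast, and the shares are not adjusted for that, so they do not exclude chance for a single list.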
